A study of Mus musculus with 19 samples.

How the data were processed

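Reduced-representation bisulfite sequencing, which reads cytosine methylation in DNA fragments cut out by restriction enzymes (here MspI and TaqαI), was applied to mouse liver. The labels describe 19 animals aged 10 months: 8 untreated wild-type (WT) mice, 6 Mat1a knockout (KO) mice given placebo and 5 Mat1a KO mice given S-adenosylmethionine (SAMe). Treatment lasted 8 weeks according to the series title. The WT animals were untreated rather than given placebo, so each WT comparison changes both genotype and the placebo or SAMe procedure. Animal codes in the labels were not replicate numbers, and no animals were paired.

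Base calling with CASAVA 1.8.2, trimming with Trim Galore, alignment with Bismark and comparison with methylKit on mm10 are named per the submitters' processing notes, which give no order or settings. The deposited data were 3 tables of the authors' own comparisons, with 1 CpG site per line. Each line held a p-value and a q-value deposited by the authors, the kind of test behind them being not given in the sources used here. The methylation difference deposited by the authors was in percentage points, running from −98.4 to 45.7 over the 3 tables. Every listed site had an absolute difference above 20 and the largest q-value listed was 0.0495. The tables held no methylation level, read coverage or value for any animal, so the depth per sample is unknown. No spread between animals, no result with an animal left out and no count of other groupings of the animals could be computed, and it is not given whether the spread between animals entered the p-values. Sites that did not pass were not listed, so a site missing from a table was either below the thresholds or not covered.

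The tables do not state which group was subtracted. At the 26 sites found in all 3 tables, the SAMe difference from WT equalled the placebo difference plus the SAMe against placebo difference within 1e-07 percentage points, so all tables use 1 orientation. Differences were read as the second group minus the first, the usual methylKit order (KO minus WT, and SAMe minus placebo among KO). If the authors used the opposite order, every direction given here turns round together. At sites listed in 2 tables the remaining difference was obtained by this addition.

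Sites were assigned to 21887 protein-coding genes of the RefSeq table for GRCm38.p6, which shares its primary coordinates with mm10, when they lay in the gene or within 2 kb of either end. The table gives no strand and no exons, so promoters, introns and exons were not distinguished, and both ends of each gene were extended in place of the planned upstream side. No genome sequence was used here. The planned background of fragments cut in silico, and with it the share of sites in promoters, was therefore replaced or left out. For the surroundings of Mat1a (10 Mb on either side) and chromosome X, genes with a listed site were counted inside and outside the region with Fisher's exact test, two-sided, and an odds ratio with a 95% interval. Every odds ratio and its interval was computed with 0.5 added to each count. This draws values from small counts towards 1, can carry them past 1 and sets the value where a count is 0.

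Before the data were examined, 14 gene lists with 387 entries were written, of which 386 matched the gene table. Each list's number of coding genes with a listed site was compared with 10000 random lists matched on gene length in 20 bins, a two-sided permutation test over genes, with Benjamini-Hochberg adjustment over 42 tests. A count adjusted over the list alone was not computed, because only listed sites carry a p-value here. Longer genes and genes rich in covered CpG sites are more often hit, and matching on length corrects the first only. The list test was tested on simulated data over 21887 genes. With no effect, p was under 0.05 in at most 2.0% of simulations. The simulated hits followed the hit rate of each length bin, as the test itself assumes. They held no bias from CpG coverage, so this share does not measure false positives from that source. With 25 genes hit at 3 times the usual rate it was under 0.05 in 88.0% for WT vs KO placebo, 73.5% for WT vs KO SAMe and 11.5% for KO placebo vs KO SAMe. At 2 times the usual rate these shares were 33.5%, 28.0% and 3.5%, so a list of 25 genes hit at that rate would usually be missed. The simulated p-values were not adjusted over the 42 tests, which lowers the shares further.

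Named sites were set by a rule fixed before the data were examined. It took the 10 largest gains and 10 largest losses in or near a coding gene in each WT comparison, and 6 and 6 between the KO groups. It also took Mat1a, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3, and the 4 members of each list with the largest absolute difference. Not every site meeting the rule is described. Some of the genes it named are not reported here. Genes of dense regions and the genes of the methionine cycle list beyond those 4 were added after their values were seen. Shares carry exact Clopper-Pearson 95% intervals, which treat sites as independent although neighbouring sites are not. Alternatives were a difference of at least 25 or 40, q under 0.001, sites merged within 1 kb, and removal of chromosomes X and Y or of the 10 Mb around Mat1a. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.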

Results

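CpG methylation in liver was compared between 8 untreated WT mice, 6 placebo-treated Mat1a KO mice and 5 SAMe-treated Mat1a KO mice, all aged 10 months. Mat1a encodes the liver form of methionine adenosyltransferase, which makes SAMe, the methyl donor for DNA methylation. The authors' tables list CpG sites past their thresholds for WT vs KO placebo, WT vs KO SAMe and KO placebo vs KO SAMe. They hold group differences without levels, coverage or spread between animals, so depth is unknown and no value below carries an SD. Directions rest on reading each difference as the second group minus the first, which the tables do not state.

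The first comparison asked how the liver methylome of placebo-treated KO mice differed from that of WT mice. Methylation was lower in the KO group at 6678 of the 6721 CpG sites in the authors' deposited table (99.4%, 95% interval 99.1 to 99.5) and higher at 43. The median difference among the lower sites was −25.9 percentage points, with quartiles of −31.9 and −22.4. A difference of at least 40 percentage points was reached at 623 sites and of at least 60 at 40 sites. Of all listed sites 69.2% lay inside a protein-coding gene, and 2745 coding genes (12.5%) had a site in the gene or within 2 kb. The sites formed 4618 regions when those within 1 kb were joined, and 3408 of these held a single site.

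**Figure D1:**
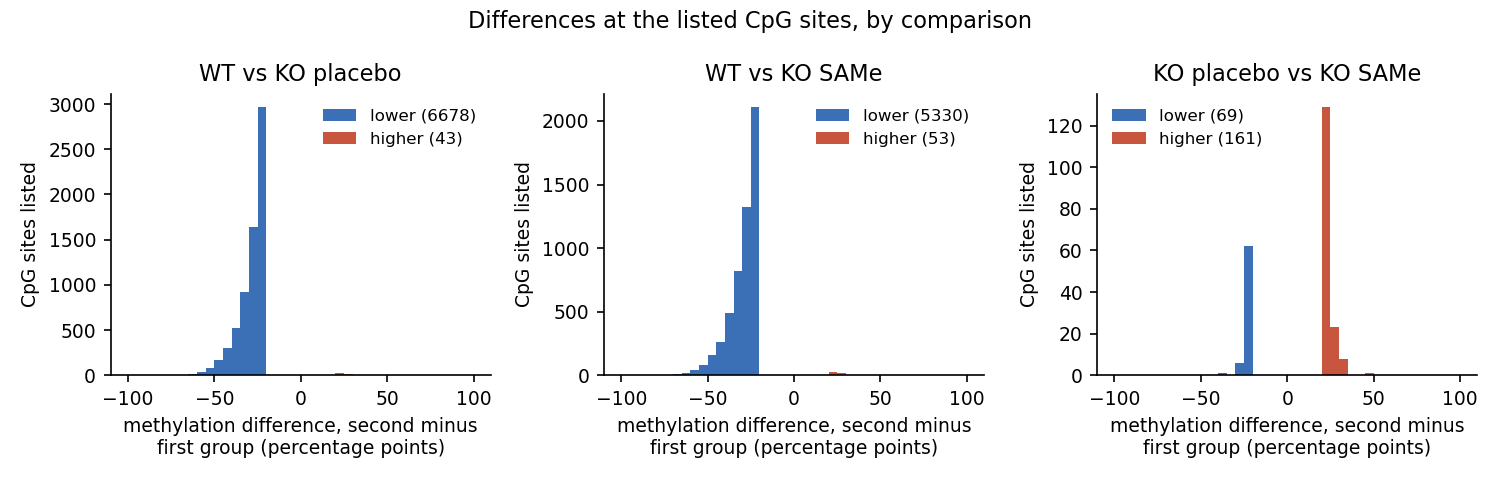
Histograms of the methylation difference (second minus first group, percentage points, bins of 5) at the CpG sites in each of the authors' tables, with the number of sites on the vertical axis. Lower sites (blue) number 6678, 5330 and 69 and higher sites (red) 43, 53 and 161, and no site lies within 20 percentage points of 0.

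Among sites in or within 2 kb of a coding gene, Arhgef40, a guanine nucleotide exchange factor, had the largest loss in placebo-treated KO liver, −97.4 percentage points at chromosome 14 position 52002288 (mm10) inside the gene, in the authors' deposited table. Shld2, a subunit of the shieldin DNA repair complex, followed at −95.5 (chromosome 14, position 34243479), and Gch1, the first enzyme of tetrahydrobiopterin synthesis, at −94.1 (position 47158699). The authors' deposited table also gave −93.3 for Rhobtb2, −87.0 for the adrenergic receptor gene Adra1a, −83.5 for Efs, −82.1 for Wdfy4 and −79.9 for a site within 2 kb of Dad1, with all q-values listed as 0. Of the 10 named losses, 9 lay on chromosome 14, which also carries Mat1a (41105012 to 41124428), and Enpp5 on chromosome 17 was the other (−72.1). Gains were fewer and smaller in the authors' deposited table. Plcg2, a phospholipase C of immune cells, gained 41.4 (chromosome 8, position 117593532), the scavenger receptor Scara5 34.6, Iffo2 33.1 and Rps6kc1 26.6. Igf2r, an imprinted receptor that clears insulin-like growth factor 2, gained 23.9 at chromosome 17 position 12741625 (q = 1.94e-06). The same site was also assigned to the imprinted gene Airn.

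Dense runs of lower sites marked several genes in WT vs KO placebo. The transcriptional regulator gene Mn1 carried 48 lower sites within 1396 bp of chromosome 5 (111418823 to 111420218), with a mean of −33.5 percentage points over the sites in the authors' deposited table. Prob1 had 29 sites with a mean of −45.9, the nuclear factor gene Nfix 22 with −38.5, Fbrsl1 20 with −48.2 and Zfp316 19 with −31.8 in the authors' deposited table. Each of these runs held lower sites only.

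No listed site lay in or within 2 kb of Mat1a, Dnmt1, Dnmt3a, Dnmt3b, Tet2 or Tet3 in any of the 3 tables. Tet1, which oxidises 5-methylcytosine, had 2 lower sites in WT vs KO placebo, the larger at −21.2, and 1 in WT vs KO SAMe at −20.3 in the authors' deposited table. A missing site does not show that methylation there was unaffected, since it may not have been covered.

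Among the gene lists, insulin and energy signalling had a listed site in 9 of 25 genes in WT vs KO placebo, against 4.25 expected from length-matched random lists (permutation p = 0.0306, adjusted p = 0.245). Its members included the forkhead factor Foxo3 (−54.6 percentage points), Irs1 (−46.6), the insulin receptor Insr (−44.2) and Igf1r (−41.3) in the authors' deposited table. The liver cancer and growth list had 13 of 45 genes with a site (6.42 expected, permutation p = 0.0152, adjusted p = 0.160), among them Dab2ip (−43.3), Trp53 (−31.7), the fetal liver marker Afp (−31.4) and Socs1 (−27.5) in the authors' deposited table. Of the 14 lists, 2 had an unadjusted p under 0.05 in the random-list test and 0 remained after adjustment. The methionine cycle list had 7 of 27 genes (3.79 expected, adjusted p = 0.558), with Shmt2, a mitochondrial serine hydroxymethyltransferase, at −46.1 and the betaine-homocysteine methyltransferase Bhmt2 at −35.8 in the authors' deposited table.

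Lipid metabolism had 10 of 43 genes with a site in WT vs KO placebo (adjusted p = 0.720), including the lipid and cholesterol regulators Srebf2 (−54.7) and Srebf1 (−36.0) in the authors' deposited table. Hepatocyte identity genes had 4 of 23, among them Prox1 (−34.1), and bile acid and drug metabolism 4 of 26, with Cyp7b1 at −27.7 and the xenobiotic receptor Nr1i2 at −26.4 in the authors' deposited table (adjusted p = 1 for both lists). The circadian clock list had 3 of 16 (Nr1d2 −45.1, Rora −37.1, Hlf −30.0 in the authors' deposited table) and the DNA methylation machinery list 2 of 17 (Mbd1 −30.6), each with adjusted p = 1. No list of markers of other liver cells passed after adjustment. Stellate cell and fibrosis genes had 6 of 27 (Smad3 −42.2, Col4a2 −40.2) and immune cell markers 2 of 33 (Csf1r −51.2) in the authors' deposited table, both with adjusted p = 0.939. Endothelial markers had 4 of 15 (Eng −38.6 in the authors' deposited table, adjusted p = 0.939). Cholangiocyte markers had 4 of 12 against 1.35 expected (Krt18 −49.0 in the authors' deposited table, permutation p = 0.0648, adjusted p = 0.357). Krt18 is also expressed by hepatocytes and held 5 of the 9 sites of this list. Imprinted genes had 6 of 31 (adjusted p = 1), with the overlapping pair Blcap and Nnat at −34.4 and Trappc9 at −35.0 in the authors' deposited table. In this list 5 genes had lower sites only. Igf2r had 3 higher sites, from 22.3 to 23.9 in the authors' deposited table, which were also assigned to Airn. Hox genes had 0 of 39 against 3.19 expected (permutation test, adjusted p = 0.357).

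**Figure D2:**
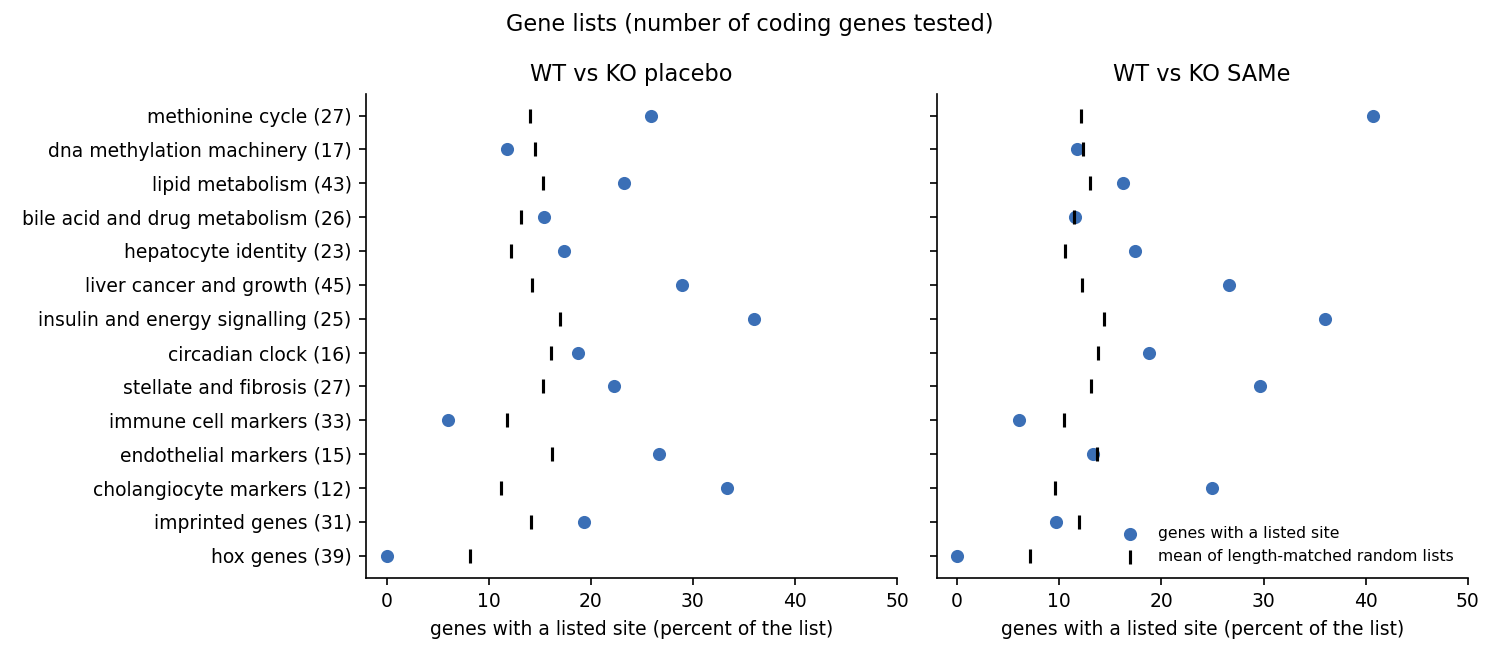
Percent of coding genes with a listed CpG site in each of the 14 gene lists (circles) and the mean percent in length-matched random lists (vertical bars), for WT vs KO placebo (left) and WT vs KO SAMe (right). The methionine cycle list stands at 25.9% and 40.7%, and Hox genes at 0 in both panels.

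The second comparison asked how SAMe-treated KO mice differed from untreated WT mice. Methylation was lower in the SAMe-treated KO group at 5330 of 5383 sites (99.0%, 95% interval 98.7 to 99.3) and higher at 53, with a median of −26.7 percentage points among lower sites in the authors' deposited table. The sites formed 3607 regions, and 2363 coding genes had a site. Among sites in or within 2 kb of a coding gene, Arhgef40 (−98.4), Shld2 (−95.7), Wdfy4 (−81.6) and Dad1 (−79.9) had the largest losses in the authors' deposited table, followed by the Golgi gene Cog5 on chromosome 12 (−78.1). Chromosome 14 held 6 of the 10 named losses. Celsr1 (−69.1), Adamts17 (−67.7) and Fndc3b (−67.3) were outside it in the authors' deposited table. Gcsh, which encodes the H protein of the glycine cleavage system, had 13 higher sites within 129 bp of chromosome 8 (116993311 to 116993439), with a mean gain of 24.4 in the authors' deposited table. Guca1b (34.3), the phosphatase gene Ctdsp1 (32.3), Plcg2 (31.6), Podxl (29.6) and Scara5 (29.5) also had gains in the authors' deposited table.

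The methionine cycle list also holds genes outside the cycle itself, such as Got1, Chdh and Mthfd1, and coverage was not matched. Its genes had listed sites more often than length-matched random lists in WT vs KO SAMe, in 11 of 27 genes against 3.27 expected (permutation p = 4e-04, adjusted p = 0.0168), and all sites were lower. They included Shmt2 (−51.0), Bhmt2 (−40.4), the glycine N-methyltransferase Gnmt (−35.8), Got1 (−32.7), Chdh (−29.0), Ahcyl1 (−28.2), Sardh (−28.0), Mthfd1 (−26.5), Ahcyl2 (−22.6) and Dmgdh (−20.9), by their lowest site in the authors' deposited table. Of these, 7 also had a site in WT vs KO placebo and 4 did not (exact two-sided p = 0.125), so a difference between the 2 comparisons was not shown. The other 13 lists did not pass after adjustment. Insulin and energy signalling had 9 of 25 genes (adjusted p = 0.160), liver cancer and growth 12 of 45 (adjusted p = 0.160) and stellate cell and fibrosis genes 8 of 27 (adjusted p = 0.245), each with an unadjusted permutation p under 0.05. Fgf21, a liver hormone of fasting, stood at −39.1 and Reln, a stellate cell gene, at −37.3 in the authors' deposited table. Hox genes again had 0 of 39 (permutation test, adjusted p = 0.459).

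Lipid metabolism had 7 of 43 genes with a site in WT vs KO SAMe, hepatocyte identity 4 of 23, bile acid and drug metabolism 3 of 26 and the circadian clock 3 of 16. Cholangiocyte markers had 3 of 12, imprinted genes 3 of 31, and the endothelial, immune cell and DNA methylation machinery lists 2 each. Srebf2 stood at −56.8, Nr1d2 at −49.0, Krt18 at −48.1, Csf1r at −44.4 and Prox1 at −41.9 in the authors' deposited table.

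Sites of the 2 WT comparisons overlapped at 3707 positions, 55.2% of the WT vs KO placebo sites and 68.9% of the WT vs KO SAMe sites. All 3707 had the same sign, 3695 lower and 12 higher. The SAMe minus placebo difference at these sites averaged −0.52 percentage points (SD 5.85 over sites), and 91.7% lay within 10. Larger differences recurred more often. The share was 36.4% of the WT vs KO placebo sites between 20 and 25 percentage points, 82.5% between 40 and 60, and 85% at 60 or more. Small differences lie close to the threshold of 20, which by itself lowers their recurrence. By addition, a site of at least 40 falling below 20 under SAMe would differ by over 20 between the KO groups. Every site of at least 40 also listed between the KO groups was listed in WT vs KO SAMe. This argues against such falls at the missing large sites, unless their q-values failed, and leaves missing coverage open. At the gene level 1861 genes had a site in both comparisons, against 296.4 for independent lists. The latter number is not matched on gene length or coverage, which raise the overlap as well. Both comparisons used the same WT animals, which adds agreement by chance, and selecting on the thresholds in both removes differing sites. Without values per animal neither part could be separated.

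**Figure D3:**
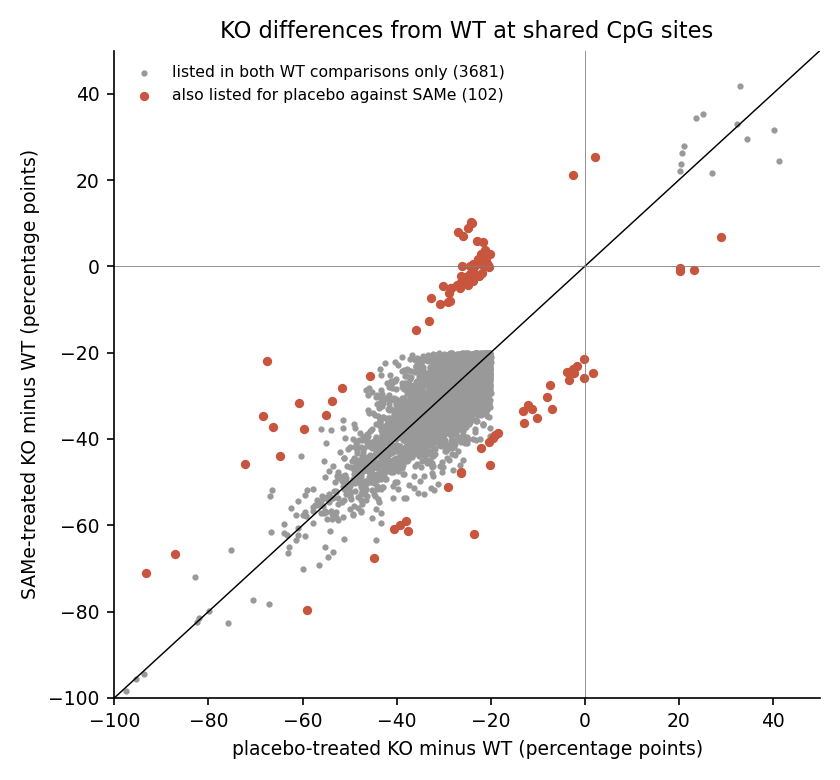
Difference of placebo-treated KO from WT (horizontal) against that of SAMe-treated KO from WT (vertical), in percentage points, per CpG site. The 3681 grey sites are listed in both WT comparisons alone, and the 102 red sites are listed between the KO groups and in at least 1 WT comparison (26 in both) and lie over 20 percentage points off the diagonal line of equality, 68 of them with SAMe-treated KO closer to WT.

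The third comparison asked what SAMe changed within KO mice. Methylation was higher with SAMe at 161 and lower at 69 of 230 sites in the authors' deposited table (30% lower, 95% interval 24.2 to 36.4). Absolute differences of at least 25 percentage points occurred at 39 sites. Jarid2, a cofactor of Polycomb repressive complex 2, had 5 sites within 23 bp of chromosome 13 (44869632 to 44869654), higher with SAMe by a mean of 33.9 in the authors' deposited table. Other sites higher with SAMe lay in Gpr180 (33.8; chromosome 14, position 118158023), Shisal1 (31.4), the cyclic nucleotide channel gene Cngb1 (31.2), Ehd2 (28.7) and Arl15 (26.8) in the authors' deposited table. Lower sites included those of Cars2, a mitochondrial cysteinyl-tRNA synthetase (−38.5), the neurexin gene Nrxn2 (−26.6), Cracr2a (−26.0), Cntn2 (−25.8), Gask1b (−25.0) and the signalling inhibitor Spry4 (−24.9) in the authors' deposited table. Of the gene lists, 5 had 1 gene each with a site and 0 of 14 had a p under 0.05 in the random-list test, before or after adjustment. They included Rora (21.8), Cd79b (21.8), Gnas (20.1) and Gata4 (−20.5) in the authors' deposited table.

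Of the 230 sites, 81 were also listed in WT vs KO placebo. At 68 of these (84.0%, 95% interval 74.1 to 91.2) the SAMe difference had the opposite sign to the KO difference: 64 were lower in KO and higher with SAMe, and 4 the reverse. The remaining 13 were lower in KO and lower still with SAMe. The 47 sites shared with WT vs KO SAMe gave the mirror image, with 34 farther from WT under SAMe (72.3%, 95% interval 57.4 to 84.4). The placebo animals enter both tables of the first pair and the SAMe animals both tables of the second, and each selection favours its own direction. Over the 102 sites in either, SAMe-treated KO was closer to WT at 68 and placebo-treated KO at 34 (66.7%, 95% interval 56.6 to 75.7; exact binomial p = 9.9e-04 against 50%, with sites taken as independent). Which table listed a site decided most of this: SAMe-treated KO was closer at all 55 sites in the placebo table alone and at 0 of 21 in the SAMe table alone. The 26 sites in both WT tables split 13 to 13 (95% interval of the share 29.9 to 70.1).

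**Figure D4:**
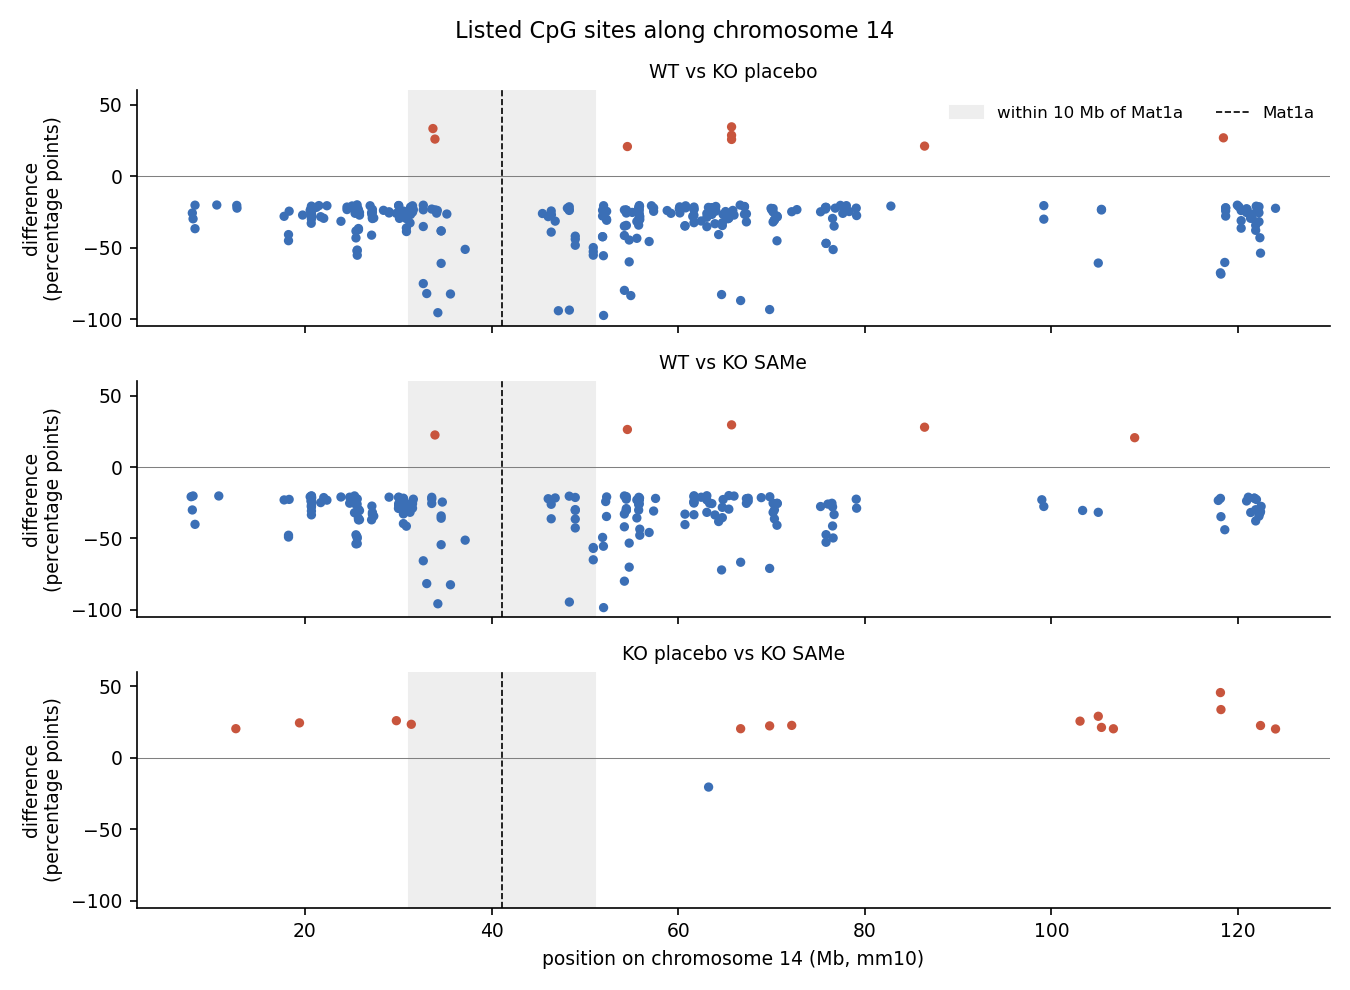
Methylation difference (percentage points) at listed CpG sites along chromosome 14 (Mb, mm10) for the 3 comparisons, with lower sites in blue and higher in red. The dashed line is Mat1a and the shaded band reaches 10 Mb to either side. Of the 16 sites in the bottom panel 15 are higher with SAMe.

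Chromosome 14 around Mat1a was compared with the rest of the genome because the KO allele lies there. Within 10 Mb, 19 of 218 coding genes (8.72%) had a site in WT vs KO placebo against 12.6% elsewhere (odds ratio 0.679, 95% interval 0.426 to 1.08, Fisher's exact p = 0.0992). In WT vs KO SAMe it was 14 of 218 genes (6.42%) against 10.8% (odds ratio 0.583, 95% interval 0.342 to 0.995, Fisher's exact p = 0.0365). Predicted genes made up 20.6% of genes inside and 5.92% outside, and without them the odds ratios were 0.826 and 0.706, with intervals holding 1. In KO placebo vs KO SAMe, 1 of 218 genes (0.459%) was inside against 0.660% elsewhere, too few to give a direction (Fisher's exact p = 1). Chromosome X had sites in 23 of 966 coding genes (2.38%) in WT vs KO placebo and 18 (1.86%) in WT vs KO SAMe, with odds ratios of 0.167 (95% interval 0.110 to 0.251) and 0.154 (0.0973 to 0.245). Between the KO groups it was 2 of 966 genes (odds ratio 0.378, Fisher's exact p = 0.0983).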

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

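The tests of large losses, of distance along chromosome 14 and of closeness to WT were chosen after the results were seen. Those of the number of genes near Mat1a and on chromosome X were planned, with genes standing in for fragments cut in silico. At 102 sites a KO difference from WT was listed and the authors' own comparison of the KO groups also passed. The deposited values there differed between the placebo-treated and SAMe-treated KO groups. No WT animals received placebo or SAMe, so whether the KO effect depends on treatment was not tested. Sampling error at single sites is not excluded either. Among the named genes the SAMe minus placebo difference in the authors' deposited table was positive for Jarid2 (34.8), Gpr180 (33.8), Ehd2 (28.7), Enpp5 (26.4), Stk19 (23.3), Rhobtb2 (22.4), Rora (21.8) and Adra1a (20.4). It was negative for Cars2 (−38.5), Nrxn2 (−26.6), Cntn2 (−25.8), Spry4 (−24.9), Tshz2 (−24.2) and Adamts17 (−22.8). At the named Jarid2 site placebo-treated KO stood at −26.8 from WT and SAMe-treated KO at 7.96 by addition.

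Regions with a loss or gain of at least 60 percentage points made up 7 of 30 regions within 10 Mb of Mat1a and 28 of 4588 elsewhere in WT vs KO placebo (odds ratio 51.1, 95% interval 20.7 to 125.7), and 6 of 19 against 28 of 3588 in WT vs KO SAMe (odds ratio 60.2). At cut-offs of 50 and 40 percentage points the odds ratios were smaller, 20.6 and 5.31 in WT vs KO placebo and 24.2 and 7.08 in WT vs KO SAMe. Of all regions of at least 60 percentage points, 17 of 35 and 12 of 34 lay on chromosome 14, so some of those counted elsewhere share the chromosome of Mat1a. The cluster was seen before these odds ratios were computed, so they describe it and are not a separate test. Loss of Mat1a acting on sites without regard to their place would not give such a cluster. An effect of the altered locus on its neighbours was not tested. A candidate explanation is sequence of another mouse strain flanking the targeted allele at genes such as Shld2 and Wdfy4. Its planned test, on the number of genes with a site, showed no excess there (odds ratios 0.679 and 0.583, and 0.826 and 0.706 without predicted genes). It does not decide the matter, because the intervals without predicted genes (0.515 to 1.32 and 0.412 to 1.21) allow some excess and coverage is unknown. The test also concerns number, not size. Over the 25 chromosome 14 regions with both WT differences known and a loss of at least 50 in either, which leaves out Gch1 and Efs, the absolute SAMe minus placebo difference rose with distance from Mat1a (Spearman rho 0.767, permutation p = 1e-05, the smallest the permutations can give and too small for linked regions), which unequal numbers of copies of a strain segment among KO animals could give, while a SAMe effect there stays open.

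SAMe-treated KO was closer to WT than placebo-treated KO at 66.7% of the 102 sites (exact binomial p = 9.9e-04 against 50%), and at 63.0% of 92 without chromosome 14 (p = 0.0160). The criterion of 50% over all sites, the first one used, decides nothing, because the table that lists a site fixes the outcome at 76 of the 102 and the placebo table is the longer (6721 against 5383 sites). Of the sites in both WT tables, a condition set after those values were seen, 13 of 26 had SAMe-treated KO closer, and 7 of 20 without chromosome 14. Sampling error in the shared placebo animals, segments of chromosome 14 and a partial effect of SAMe are all left open.

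An imbalance of the sexes between the groups predicted an excess of genes with a site on chromosome X, and the odds ratios of 0.167 and 0.154 showed none. They go against an imbalance large enough to give such an excess among listed sites. A partial imbalance is not excluded, because only differences above 20 percentage points are listed and the coverage of chromosome X is unknown.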

How the results depend on the processing

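Of 86 recomputed values, 67 kept their direction and size or side of the threshold. The odds ratios of large losses near Mat1a counted as kept because they stayed above 1 with Fisher's exact p under 0.05, though they fell at lower cut-offs. Not all of the 67 were free to change. Overlap by identical coordinates equals the main result by construction, and merging sites within 1 kb left the gene-level odds ratios near Mat1a and on chromosome X as they were. Removal of predicted genes, of the whole of chromosome 14, use of sites inside genes only, other cut-offs for large losses, other selections of chromosome 14 regions and merging for the share of returning sites were added after the data were seen. The number of sites fell by construction when a difference of at least 25 was asked for (3730, 3247 and 39 in the order of the 3 comparisons) or of at least 40 (623, 582 and 1), and the share lower was then 99.7%, 99.8% and 0% at 40, and 17.9% at 25 between the KO groups. With q under 0.001 the KO groups differed at 122 sites, and 51 in place of 81 were shared with WT vs KO placebo, the share returning towards WT being 86.3%. The odds ratio of genes near Mat1a in WT vs KO placebo was 1.06 at 20 Mb. At 5 Mb 0 of 80 genes had a site in either WT comparison, fewer than elsewhere by Fisher's exact test (p = 5.0e-05 and 1.9e-04, and 0.00725 and 0.0185 without the 52.5% that were predicted genes). The odds ratios there, 0.0431 and 0.0511, take their size from the constant added to 0. The odds ratio was 0.955 at 20 Mb and 0.706 without predicted genes in WT vs KO SAMe, and 0.931 at 5 Mb, 0.487 at 20 Mb and 0.743 with q under 0.001 between the KO groups, where 0 or 1 gene had a site and the added constant sets the value and its side of 1. The cause was not tested. The methionine cycle list passed in WT vs KO SAMe under all 3 alternatives run. Promoter shares, promoter-only lists and other fragment sizes were not run because no genome or strand was used here. Overlap by shared length equals the main result for single sites. No paired analysis was possible because the tables hold no values per animal, which also rules out leaving out animals. Depth is unknown, and its limit on missed sites could not be set.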

Other observations

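The tests here were chosen after the data were seen. At 128 of the 230 sites between the KO groups neither WT comparison listed the site, and 95 of these were higher with SAMe.

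The weakest listed site of KO placebo vs KO SAMe had a p-value of 0.00332 and a q-value of 0.0495, a ratio of 6.71%, against 21.7% in WT vs KO placebo and 21.2% in WT vs KO SAMe, in the authors' deposited table. For q-values of the Benjamini-Hochberg kind, this ratio bounds the share of all tested sites with a p-value that small. The method behind the q-values is not given in the sources used here.

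Among the 3707 sites shared by the WT comparisons, 4 had differences equal within 1e-06 percentage points, 3 of them on chromosome 14 and 2 of these within 10 Mb of Mat1a, where 26 shared sites lay (Fisher's exact p = 2.8e-04). They included the site near Dad1 (−79.9 in both comparisons in the authors' deposited table). Equal differences mean equal levels in the KO groups at these sites. Over the chromosome 14 regions with both WT differences known and a loss of at least 50 percentage points in either, the median absolute SAMe minus placebo difference was 0.653 in the 8 within 10 Mb of Mat1a (Gch1, listed for placebo alone, is not among them), against 6.88 in 114 such regions of other chromosomes. The 5 beyond 60 Mb were higher with SAMe by 16.4 to 45.7, and rho was 0.728 without the 2 regions farthest from the median distance. Asking for a mean loss of at least 50 over both WT comparisons left 20 regions, 2 of them beyond 60 Mb, with a rho of 0.693.

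Large differences also gathered on chromosome 12 between 30 and 35 Mb in WT vs KO SAMe, where 4 of 5 regions reached 60 percentage points (permutation p = 0.0074 over windows of 5 Mb), among them that of Cog5. In WT vs KO placebo the same window held 3 of 10 such regions (permutation p = 0.115). On chromosome 14 the scan gave 4 of 14 regions between 50 and 55 Mb in WT vs KO SAMe (permutation p = 0.0074) and 3 of 16 in WT vs KO placebo (permutation p = 0.115). Between 30 and 35 Mb of chromosome 14 it was 4 of 22 in WT vs KO placebo (permutation p = 0.0082) and 3 of 17 in WT vs KO SAMe (permutation p = 0.116). Mat1a is not on chromosome 12, so a segment flanking its targeted allele does not reach the chromosome 12 window, and no explanation was tested.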
